A study of Mus musculus with 8 samples.

How the data were processed

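Messenger RNA was sequenced from mouse alveolar macrophages, the resident macrophages of the lung air spaces, in 4 WT and 4 Batf2-/- libraries. Per the labels, all cells received interferon gamma at 10 ng/mL for 4 h and then 20% Klebsiella pneumoniae culture supernatant for 6 h, and each library came from cells pooled from 4 mice. RNA was extracted with a column kit and libraries were made with a stranded mRNA kit, per the labels' protocols. The deposited values were raw total counts of reads per gene, per the file header, with no normalization. The genome build was GRCm38, also called mm10, per the submitters' processing notes. The aligner, the counting tool, the strand setting of the count and the annotation release were not given in the sources used here, so counts of genes that overlap on opposite strands, such as Batf2 and Arl2, and of near-identical copies were treated as uncertain.

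The deposited table held 48709 genes with symbols and Ensembl identifiers, of which 48349 identifiers matched the reference annotation of GRCm38. Its 8 count columns stood under a heading for each genotype, 4 under each, and were assigned to groups by that heading. The columns carried no replicate number from the labels, so libraries are numbered here by table column, 1 to 4 for WT and 5 to 8 for Batf2-/-, and no library was matched to a labelled replicate. The total count per library ranged from 31730041 to 39888022. Counts of pairs of libraries within a group differed by far more than sampling noise, with chi-square values over degrees of freedom of 32.1 or more, so all 8 were counted as separate samples. Each library was a pool, so the spread between libraries is a spread between pools and not between single mice.

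The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with robust dispersions, TMM factors, the default expression filter and genotype as the only term. The filter left 11083 genes, and p-values were adjusted over them by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are Batf2-/- over WT. CPM values are counts scaled to a common library size with the TMM factors and are given as mean ± SD over n = 4 libraries. A gene with 0 counts in a whole group was given a bound computed against a floor of 3 counts over that group, which covers counting error only. Samples of a group are called non-overlapping where all 4 libraries lie beyond all 4 of the other group.

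Before the data were examined, 37 gene lists were fixed, covering macrophage activation, chemokines, interferon response, antigen presentation, transcription factors, pathogen sensing, bacterial killing, metabolism, RNA quality, other cell types and the neighbours of Batf2. The 33 lists with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it, and members were also counted as adjusted over the list alone. The genes to be named were fixed by a rule: Batf2, the 12 largest rises and 12 largest falls among genes with an adjusted p under 0.05, a mean log2 CPM of at least 2 and non-overlapping groups, up to 4 members of each list with the smallest adjusted p, and Nos2, Il12b, Il6, Tnf, Il1b, Cxcl9, Ccl5, Arg1, Mrc1, Irf1, Batf and Batf3. Not all list members the rule allows are printed, and those printed were chosen among them after their values were seen. Genes outside the rule were chosen after their values were seen and are marked as such.

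The procedure was tested on counts simulated for the real genes and libraries, with 11006 genes passing the filter. Without a shared deviation between libraries, 84% of genes changed 2-fold and 98% of genes changed 4-fold were recovered, 2% of genes changed 1.5-fold were recovered, and 6.06% of calls were false. The alternatives fixed beforehand were DESeq2 1.42.0, limma-voom with and without library quality weights, other normalizations, no filter and a stricter filter, a block on replicate numbers, a test against a 1.5-fold change, an adjusted p under 0.01 and leaving out each library in turn. Alternatives added after the data were seen were a block on column position, the sex of the pools as a covariate, leaving out libraries 4 and 8, and leaving out chromosomes 11 and 19. Gene coordinates were taken from the reference annotation of GRCm38.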

Results

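The transcriptomes of stimulated alveolar macrophages were measured to ask how BATF2, a transcription factor of the AP-1 family, affects macrophage polarization. Primary cells from WT and Batf2-/- mice were given interferon gamma and then supernatant of Klebsiella pneumoniae, a Gram-negative lung pathogen, and 4 libraries per genotype were compared. No unstimulated cells were part of the comparison. Total counts ranged from 31730041 to 39888022 per library, and between 13516 and 14157 genes had at least 1 count. The first principal component of log2 CPM held 42.5% of the variance. Its scores rose in order of table column within each genotype, with library 4 (WT) and library 8 (Batf2-/-) highest. They were -16.72, -7.734, 4.718 and 43.9 in libraries 1 to 4, and -34.95, -16.24, -1.849 and 28.87 in libraries 5 to 8. The second component held 24.2% and separated the genotypes. By Xist and Y-linked genes, 2 pools of each genotype were female and 2 were male.

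**Figure D1:**
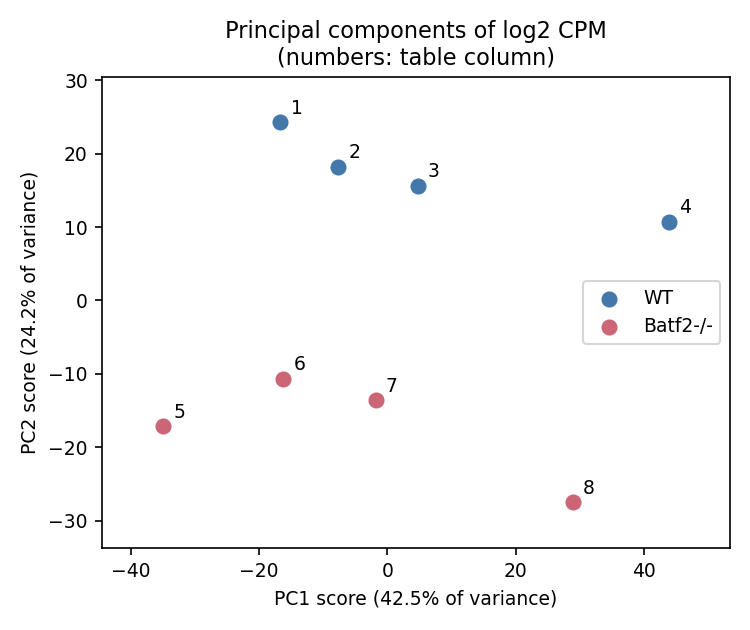
Scores of the 8 libraries on the first (x axis, 42.5% of variance) and second (y axis, 24.2%) principal components of log2 CPM, with WT in blue and Batf2-/- in red, each point numbered by its table column. Libraries 4 and 8 lie to the right with scores of 43.9 and 28.9, and all 4 WT libraries lie above all 4 Batf2-/- libraries on the second component.

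Batf2 itself was lost. Batf2 (ENSMUSG00000039699; GRCm38 chromosome 19, 6140983 to 6172476, plus strand) had 0 counts in each of the 4 Batf2-/- libraries. In WT it stood at 189, 178, 168 and 138 CPM in libraries 1 to 4, a mean of 168 ± 21.9 CPM (SD, n = 4), so its level was at least 8240-fold lower in Batf2-/- against a floor of 3 counts over the group (edgeR adjusted p = 2.08e-05). Majin, a meiotic telomere gene that starts downstream of Batf2 on the same strand at 6184388, also had 0 counts in all 4 Batf2-/- libraries against 0.488 ± 0.114 CPM in WT, at least 23.9-fold lower against the same floor (adjusted p = 0.00784). Snx15, a sorting nexin gene on the opposite strand, starts upstream of Batf2 at 6128304. It fell from 26.8 ± 3.06 to 15.9 ± 2.13 CPM (adjusted p = 0.0316). Its call ended, with adjusted p between 0.0834 and 0.132, without library 1, 2, 3, 5 or 7. Arl2, which overlaps Batf2 on the opposite strand, did not pass, at 20.7 ± 3.29 CPM in WT and 15.3 ± 2.06 CPM in Batf2-/- (adjusted p = 0.335). Of the 32 tested members of the list of Batf2 neighbours, 2 fell, none rose and 30 did not pass, and adjusted over the list alone the counts were the same, 0 and 2. The list as a whole did not pass (camera adjusted p = 0.609), and its median lay above 0 while its mean and camera direction lay below.

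**Figure D2:**
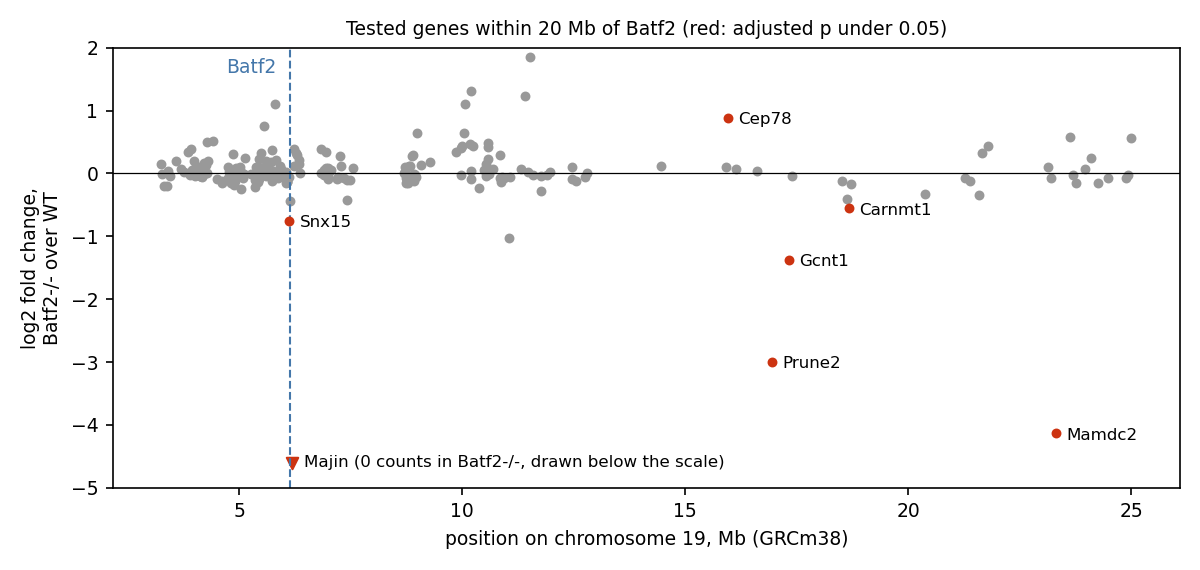
Log2 fold change (y axis, Batf2-/- over WT) of each tested gene within 20 Mb of Batf2 by its position on chromosome 19 (x axis, Mb, GRCm38), with genes at an adjusted p under 0.05 in red and the start of Batf2 as a dashed line. Apart from Batf2, 7 of 234 genes are red, and Majin, with 0 counts in Batf2-/-, is drawn as a triangle below the scale; Carnmt1, Cep78 and Mamdc2 were labelled because they passed, after their values were seen.

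Across all genes, 123 of 11083 changed between genotypes by edgeR's quasi-likelihood test, 61 higher and 62 lower in Batf2-/-, and 942 genes had an unadjusted p under 0.05. Of the 123 genes, 76 changed at least 2-fold. All 123 had non-overlapping groups, as did 6.33% of all tested genes, where chance gives 2.86%. Leaving out single libraries gave between 43 genes (without library 3) and 142 genes (without library 8). The counts were 76, 63, 76, 77 and 59 without libraries 1, 2, 5, 6 and 7, and 103 without library 4. DESeq2 gave 212 higher and 131 lower genes, limma-voom with library quality weights 227 and 143, the fit without libraries 4 and 8 133 and 73, and a block on table position 772 and 618. The fits without libraries 4 and 8 and with the block were chosen after the data were seen, and the labels do not give the pairing by table position.

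Among changed genes with a mean log2 CPM of at least 2 and non-overlapping groups, the 12 largest rises included those of Il1b and Ccl4. Gm8797, a predicted gene, rose from 1.07 ± 0.407 to 23.3 ± 2.96 CPM (SD, n = 4 per group; edgeR adjusted p = 7.34e-05). Nr4a3, a nuclear receptor gene induced early after stimulation, rose 3.92-fold (adjusted p = 0.0269), and Xrcc5, which encodes the Ku80 subunit of the DNA end-joining machinery, rose 3.42-fold (adjusted p = 3.93e-04). Slc43a2, a transporter of neutral amino acids, rose 3.22-fold. Ccl4, a chemokine for monocytes and T cells, rose 2.83-fold from 35.1 ± 3.76 to 99.3 ± 22.2 CPM (adjusted p = 0.00446). Il1b, the gene for interleukin 1 beta, rose 2.68-fold from 112 ± 22.6 to 301 ± 50.3 CPM (adjusted p = 0.00626). The other rises of the 12 largest were those of Spata13 (3.16-fold), Pkdcc (2.95-fold), Dok7 (2.78-fold), Akap2 (2.47-fold), Col5a3 (2.43-fold) and Cd38 (2.42-fold). Dok7 and Col5a3 had an adjusted p of 0.0475 and lost the call without any of libraries 1 to 7 (adjusted p from 0.0705 to 0.177). Spata13 lost it without library 3 (0.0657), Pkdcc without library 3 or 7 (0.0505 and 0.0555) and Akap2 without library 1 or 3 (0.0590 and 0.0824). The same held for Nr4a3 without library 2, 3, 5, 6 or 7 (0.0676 to 0.115) and Cd38 without library 2, 3, 4, 6 or 7 (0.0529 to 0.121).

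Within the same limits of level and non-overlap, the 12 largest falls included those of Vcam1, Cd180, Jdp2 and Il27. Prune2 fell 7.95-fold from 14.9 ± 2.26 to 1.86 ± 0.885 CPM (SD, n = 4 per group, edgeR adjusted p = 0.00131). It lies within 20 Mb of Batf2, as does Gcnt1 below. Vcam1, an adhesion molecule for leukocytes, fell 3.55-fold from 21.1 ± 4.28 to 5.96 ± 1.11 CPM (adjusted p = 0.00208). Cd180, a toll-like receptor homologue, fell 2.98-fold from 52.7 ± 9.39 to 17.6 ± 5.26 CPM (adjusted p = 0.0103). Jdp2, a bZIP repressor that pairs with AP-1 members, fell 2.37-fold from 17.5 ± 1.51 to 7.39 ± 0.700 CPM (adjusted p = 0.00115). Il27, a subunit of interleukin 27, fell 2.29-fold from 78.5 ± 7.003 to 34.2 ± 6.86 CPM (adjusted p = 0.00670). The other falls of the 12 largest were those of Sgsm2 (3.12-fold), Nadk2, the mitochondrial NAD kinase (2.92-fold), Pttg1, the securin gene (2.74-fold), Gcnt1, a glycosyltransferase (2.59-fold), Endod1 (2.58-fold), Zranb3 (2.45-fold) and Tifab (2.37-fold). Cd180 lost the call without library 3 or 7 (adjusted p = 0.0505 and 0.0555), Endod1 without library 3, 6 or 7 (0.0585 to 0.0740) and Tifab without library 1, 2, 3 or 6 (0.0707 to 0.0901).

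**Figure D3:**
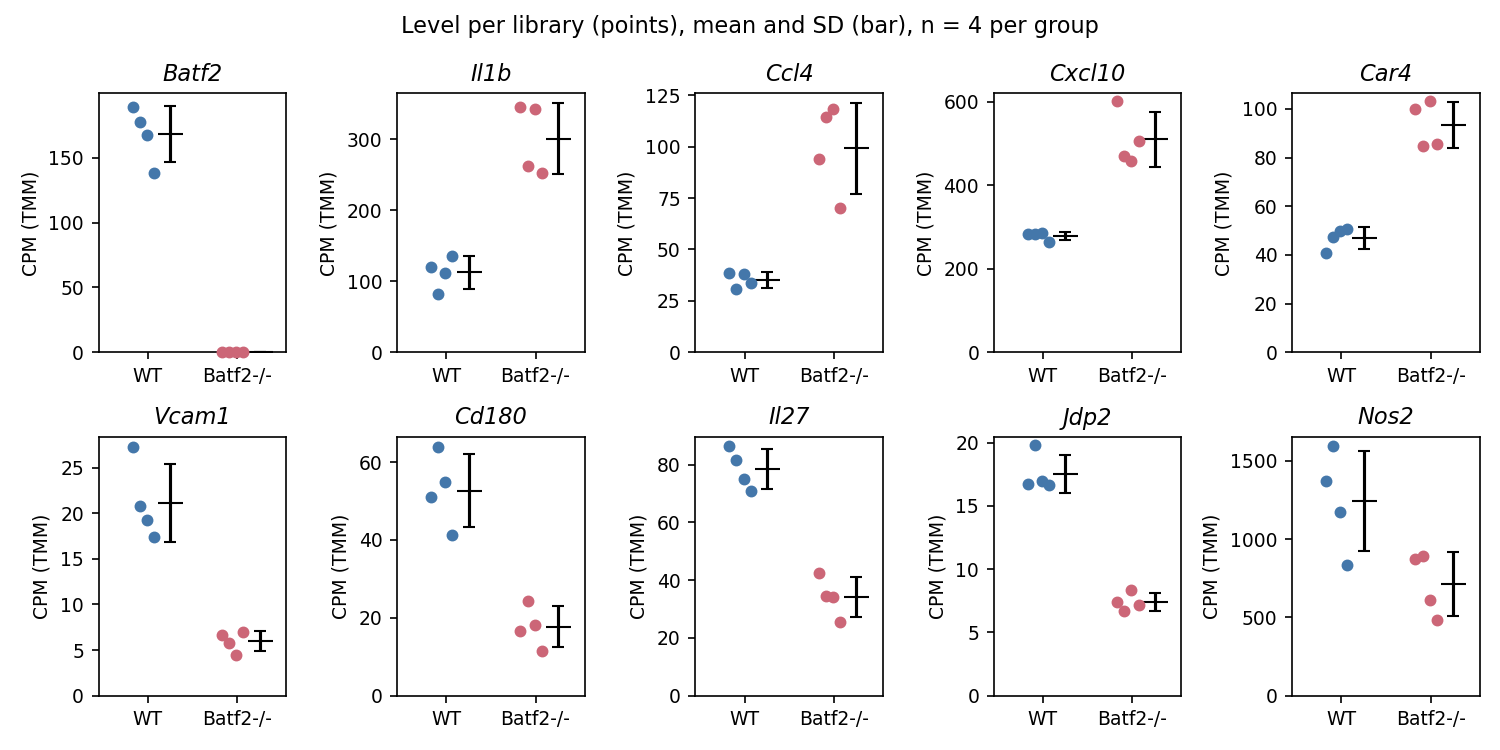
CPM (y axes, from 0) of 10 named genes in each of the 4 WT (blue) and 4 Batf2-/- (red) libraries, with the group mean and SD as a black bar. Il1b, Ccl4, Cxcl10 and Car4 were higher and Vcam1, Cd180, Il27 and Jdp2 lower in all 4 Batf2-/- libraries than in any WT library, Batf2 was at 0 in all 4, and Nos2 overlapped between groups.

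Changed genes were unevenly spread over chromosomes. Chromosome 11 held 23 changed genes among 933 tested (2.46%; Fisher's exact test, two-sided, adjusted over 20 chromosomes, p = 0.00477), against 1.11% of all tested genes. Slc43a2, Ccl4, Sgsm2 and Pttg1 lay there, as did Car4, Igtp and Nlrp1b, whose values follow. Chromosome 19, which carries Batf2, held 10 of 410 (2.44%; adjusted p = 0.115), among them Prune2 and Gcnt1. Chromosome 8 held 0 of 609 (adjusted p = 0.0205) and chromosome 7 held 2 of 869 (adjusted p = 0.0401).

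Effectors of classical activation moved in both directions. Of 29 tested members, 4 rose, 1 fell and 24 did not pass, and 5 rose and 3 fell adjusted over the list alone. Il1b and Cd38 rose as given above, Cxcl10, a T cell chemokine, rose 1.83-fold from 279 ± 10.0 to 510 ± 65.4 CPM (SD, n = 4; edgeR adjusted p = 0.00802), and Il23a rose 4.57-fold at a low level, from 0.0904 ± 0.0361 to 0.424 ± 0.0741 CPM (adjusted p = 0.0183). Il27 fell. Nos2, the inducible nitric oxide synthase, did not pass at 1243 ± 322 CPM in WT and 715 ± 203 CPM in Batf2-/- (adjusted p = 0.270), nor did Il12b at 77.0 ± 8.65 and 50.4 ± 13.7 CPM (adjusted p = 0.251), Il6 at 121 ± 32.1 and 85.8 ± 16.2 CPM (adjusted p = 0.568) or Tnf at 4206 ± 259 and 3149 ± 573 CPM (adjusted p = 0.357). With table position as a block, a pairing chosen after the data were seen and not given by the labels, Nos2 passed at an adjusted p of 9.84e-06 (9.84e-06 to 1 over its 20 alternatives), Tnf at 0.00311 (up to 1) and Il6 at 0.00568 (up to 1), all lower in Batf2-/-. Il12b passed in none of its 20 alternatives (lowest adjusted p = 0.0610). With the block, 9 members of the list rose and 7 fell. Cxcl9 stood at 4103 ± 259 and 4908 ± 443 CPM (adjusted p = 0.571) and Ccl5 at 69.1 ± 17.9 and 69.3 ± 22.8 CPM (adjusted p = 1.00). The list did not pass as a whole by camera, which tests a shift in 1 direction (adjusted p = 0.429). Fry without regard to direction gave an adjusted p of 1.29e-06, a result that a few changed members can carry. Cxcl10 lost its call without library 3 (adjusted p = 0.0503). The Il23a log2 fold change lost it without library 1, 2, 5 or 6 (0.0556 to 0.0707) and without libraries 4 and 8 together (0.0525).

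Chemokines for T and NK cells passed as a list in the upward direction (camera adjusted p = 3.85e-04, or 0.187 with an estimated correlation). Of 7 tested members 1 rose (Cxcl10) and none fell, with 2 rising adjusted over the list alone. Neutrophil and stromal markers also passed upward as lists (camera adjusted p = 0.00684 and 0.0190, or 0.187 and 0.368 with an estimated correlation). Ccl17 stood at 0.221 ± 0.1204 CPM in WT and 0.923 ± 0.659 CPM in Batf2-/- (edgeR adjusted p = 0.185) and Ccl22 at 11.5 ± 2.45 and 19.9 ± 12.4 CPM (adjusted p = 0.629). Of 16 tested chemokines and growth factors for neutrophils and monocytes, 1 rose (Ccl4) and 15 did not pass, with 4 rising and 2 falling adjusted over the list alone (camera adjusted p = 0.0722). Ccl3 stood at 214 ± 32.8 and 360 ± 88.2 CPM (adjusted p = 0.170) and Csf3 at 0.614 ± 0.125 and 1.45 ± 0.497 CPM (adjusted p = 0.121). Among markers of alternative activation, 0 of 18 tested members passed by edgeR and 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.668). Chil3 stood at 3316 ± 613 and 6291 ± 2055 CPM (adjusted p = 0.147), Mrc1, the mannose receptor, was at 645 ± 104 and 644 ± 103 CPM (adjusted p = 1.00), and Arg1 did not pass the filter.

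Among interferon-inducible GTPases, which act against intracellular pathogens, 1 of 24 tested members rose, 1 fell and 22 did not pass, with 2 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.0888). Igtp, also called Irgm3, rose 1.58-fold from 260 ± 6.61 to 411 ± 31.7 CPM (SD, n = 4; edgeR adjusted p = 0.0151) and Gbp4 fell 1.95-fold from 139 ± 18.2 to 71.2 ± 12.8 CPM (adjusted p = 0.0183). These families hold near-identical copies, so reads can be split between members. Igtp lost the call without library 1, 2, 3 or 7 (0.0590 to 0.0901) and Gbp4 without library 2, 3, 5, 6 or 7 (0.0506 to 0.127). In the type I interferon list, 0 of 48 tested members passed, also adjusted over the list alone, with a median log2 fold change of -0.09 (camera adjusted p = 0.0635). In alternatives chosen after the data were seen, this list passed downward without chromosomes 11 and 19 (camera adjusted p = 0.0383) and without libraries 4 and 8 (0.0327). Ifi205 stood at 249 ± 26.8 and 171 ± 32.3 CPM (adjusted p = 0.221), Rtp4 at 47.8 ± 6.71 and 31.8 ± 7.51 CPM (adjusted p = 0.283) and Xaf1 at 49.5 ± 5.82 and 80.7 ± 20.9 CPM (adjusted p = 0.139).

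MHC class II presentation passed as a list in the downward direction (camera adjusted p = 0.0124, or 0.245 with an estimated correlation). Even so, 0 of its 16 tested members passed, over all genes or adjusted over the list alone. With table position as a block 5 fell, and the camera adjusted p was 0.0181, or 0.561 with an estimated correlation. H2-Aa stood at 901 ± 189 CPM in WT and 704 ± 121 CPM in Batf2-/- (SD, n = 4; edgeR adjusted p = 0.727), H2-Eb1 at 405 ± 78.2 and 326 ± 51.9 CPM (adjusted p = 0.771), and Ciita, the master regulator of class II genes, at 68.8 ± 11.7 and 56.4 ± 7.13 CPM (adjusted p = 0.750). Clec9a, a dendritic cell marker, fell from 2.46 ± 0.130 to 0.253 ± 0.0717 CPM (adjusted p = 1.20e-04). Of the 8 tested dendritic cell markers another 1, Zbtb46, went the other way. It rose adjusted over the list alone, from 0.937 ± 0.2625 to 1.92 ± 0.348 CPM with non-overlapping groups (edgeR adjusted p = 0.0965 over all genes). That list did not pass (camera adjusted p = 0.628). The neutrophil and stromal marker lists passed upward (camera adjusted p = 0.00684 and 0.0190, or 0.187 and 0.368 with an estimated correlation). None of 23 MHC class I members passed, also adjusted over the list alone (camera adjusted p = 0.880).

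Among AP-1 and ATF factors, 2 of 28 tested members fell, Jdp2 and Creb1, and none rose, with the same counts adjusted over the list alone (camera adjusted p = 0.219). Creb1 fell 1.48-fold from 78.0 ± 5.25 to 52.7 ± 5.62 CPM (SD, n = 4; edgeR adjusted p = 0.0498) and lost the call without any of libraries 1 to 7 (0.107 to 0.236). Batf, a paralogue of Batf2, stood at 29.1 ± 9.09 and 32.2 ± 8.13 CPM (adjusted p = 1.00), Batf3 at 5.43 ± 1.51 and 8.59 ± 1.88 CPM (adjusted p = 0.317) and Cebpd at 22.5 ± 1.39 and 16.8 ± 2.24 CPM (adjusted p = 0.225). None of 23 IRF and STAT factors passed, also adjusted over the list alone (camera adjusted p = 0.790), with Irf1 at 1462 ± 147 and 1428 ± 156 CPM. Of 33 NF-kB subunits and feedback genes, none passed and 2 rose adjusted over the list alone (camera adjusted p = 0.0930), Tnip1 at 162 ± 21.4 and 254 ± 38.1 CPM and Marcks at 15.6 ± 1.93 and 24.3 ± 3.93 CPM. Of 28 toll-like receptor sensing genes, 1 fell (Cd180) and 27 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.790), with Cd14 at 154 ± 33.7 and 260 ± 78.2 CPM (adjusted p = 0.254).

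The lists of inflammasome, bacterial killing and receptor genes passed in the upward direction, as did neutrophil markers (camera adjusted p = 0.00684; adjusted p = 0.187 with an estimated correlation) and stromal and endothelial markers (camera adjusted p = 0.0190; adjusted p = 0.368 with an estimated correlation). Inflammasome and pyroptosis genes passed with 2 of 21 tested members rising and 19 not passing, and 2 rising adjusted over the list alone (camera adjusted p = 0.0399; adjusted p = 0.230 with an estimated correlation). Without the genes of chromosomes 11 and 19, an alternative chosen after the data were seen, this list did not pass (camera adjusted p = 0.223). These were Il1b and Nlrp1b, an inflammasome sensor that rose 8.64-fold at a low level, from 0.128 ± 0.0687 to 1.15 ± 0.170 CPM (SD, n = 4; edgeR adjusted p = 0.00276). Bacterial killing and iron genes passed upward, with 1 of 22 rising and 21 not passing, and 4 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.0140; adjusted p = 0.216 with an estimated correlation). Slpi, a secreted protease inhibitor, rose 1.55-fold from 157 ± 17.6 to 244 ± 12.4 CPM (adjusted p = 0.0332) and lost the call without any library but library 4 (0.0509 to 0.133). Acod1, which makes itaconate, stood at 2989 ± 390 and 4430 ± 713 CPM (adjusted p = 0.180). Phagocytic and scavenger receptors passed upward, with 2 of 26 rising and 24 not passing, and 4 rising adjusted over the list alone (camera adjusted p = 0.0124; adjusted p = 0.245 with an estimated correlation). Fcgr2b, the inhibitory Fc receptor, rose 1.71-fold from 52.9 ± 5.37 to 90.2 ± 13.6 CPM (adjusted p = 0.0285) and Trem1, an amplifier of inflammation, rose 3.73-fold from 0.541 ± 0.156 to 2.03 ± 0.599 CPM (adjusted p = 0.0141). Fcgr2b lost the call without library 1, 2, 3, 5, 6 or 7 (0.0547 to 0.0901) and Trem1 without library 2 or 3 (0.0576 and 0.0816).

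Among 38 tested genes of alveolar macrophage identity, 1 rose and 37 did not pass, with 3 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.0888). Car4, a carbonic anhydrase of these cells, rose 1.98-fold from 47.1 ± 4.55 to 93.4 ± 9.60 CPM (SD, n = 4; edgeR adjusted p = 0.00501). In the metabolic lists no tested member passed over all genes, with camera adjusted p of 0.118 for 30 glycolysis and HIF-1 genes, 0.880 for 39 oxidative phosphorylation genes, 0.0934 for 32 cholesterol and lipid synthesis genes and 0.0722 for 21 LXR and PPAR targets. Adjusted over the list alone, Hif1a was lower in Batf2-/- at 620 ± 55.0 and 415 ± 33.7 CPM (adjusted p = 0.0503 over all genes), Srebf1, on chromosome 11, was higher at 38.7 ± 9.20 and 80.4 ± 18.2 CPM (0.0581), and Abca1 was higher at 10.1 ± 3.28 and 24.7 ± 8.21 CPM (0.0824). The NRF2 response (23 tested, camera adjusted p = 0.880), unfolded protein response (24, 0.790), cell cycle (31, 0.945), immediate early and heat shock (19, 0.187) and mitochondrial transcript (13, 0.273) lists had no passing member, also adjusted over the list alone. With table position as a block, mitochondrial transcripts passed in the downward direction with 7 of 13 falling (camera adjusted p = 0.00897; adjusted p = 0.649 with an estimated correlation). Likewise, cholesterol and lipid synthesis passed upward with 7 of 32 rising and 2 falling (camera adjusted p = 0.0362; adjusted p = 0.561 with an estimated correlation).

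**Figure D4:**
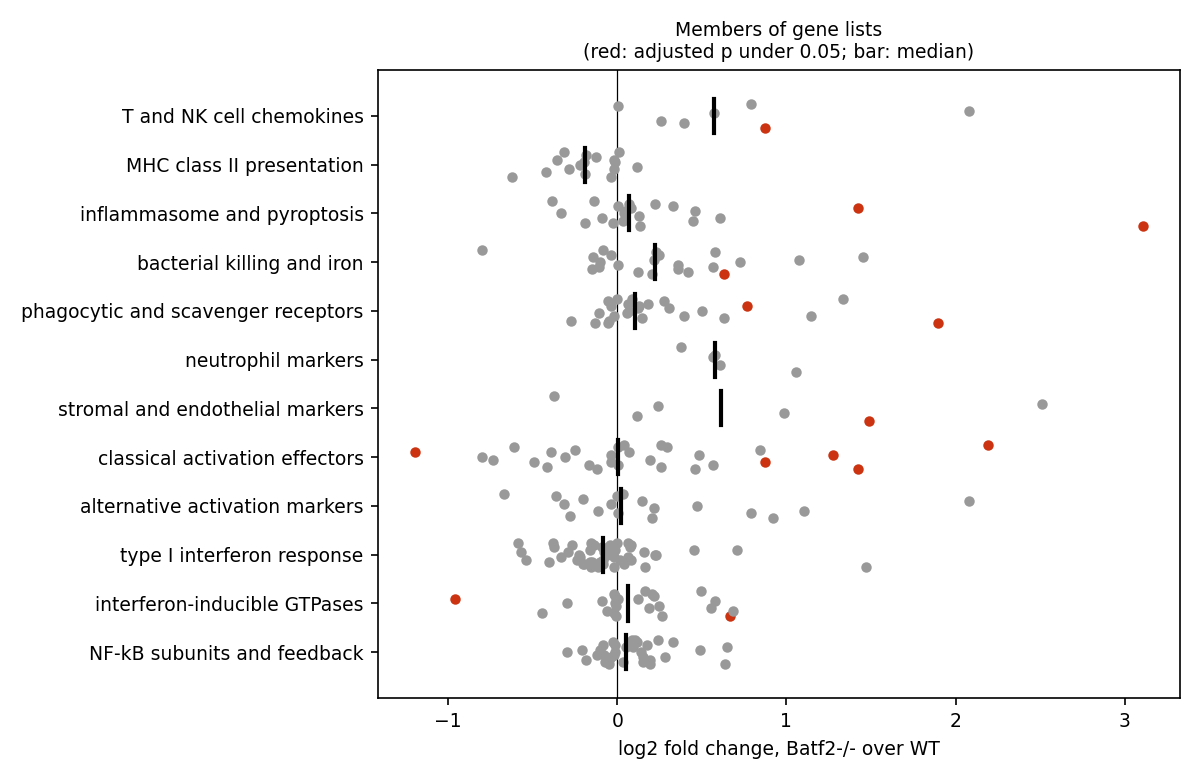
Log2 fold change of each tested member (points, Batf2-/- over WT, x axis) for 12 gene lists (y axis), with members at an adjusted p under 0.05 in red and the list median as a black bar. The classical activation effectors hold 4 members in red above 0 and 1 below, and the median of the T and NK cell chemokines lies at 0.57.

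Some markers of other cell types moved with genotype. Neutrophil markers passed as a list in the upward direction with 0 of 5 tested members passing over all genes and 1 rising adjusted over the list alone (camera adjusted p = 0.00684, or 0.187 with an estimated correlation). Only these 5 of the 21 listed markers passed the filter. S100a8 stood at 19.2 ± 6.98 and 29.2 ± 11.9 CPM (SD, n = 4; edgeR adjusted p = 0.699), Mcemp1 at 30.3 ± 6.96 and 45.2 ± 17.2 CPM (adjusted p = 0.572) and Cxcr2 at 2.89 ± 0.813 and 6.03 ± 1.68 CPM (adjusted p = 0.122). With table position as a block, a pairing not given by the labels, 3 of the 5 neutrophil markers rose and none fell. The list then had a camera adjusted p of 0.00721, or 0.561 with an estimated correlation. Stromal and endothelial markers also passed upward, with 1 of 6 tested members rising and 3 rising adjusted over the list alone (camera adjusted p = 0.0190, or 0.368 with an estimated correlation). Here 6 of the 19 listed markers passed the filter. Pdgfrb rose 2.81-fold at a low level, from 0.708 ± 0.205 to 2.00 ± 0.548 CPM (adjusted p = 0.0376), and Cdh5 stood at 0.276 ± 0.162 and 1.596 ± 1.18 CPM (adjusted p = 0.112). Pdgfrb lost the call without library 2, 3, 4, 5, 6 or 7 (0.0748 to 0.161). Of 8 dendritic cell markers, 1 fell, and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.628). The fall was that of Clec9a, from 2.46 ± 0.130 to 0.253 ± 0.0717 CPM (adjusted p = 1.20e-04), and the rise that of Zbtb46. The T cell (4 tested, camera adjusted p = 0.0722), monocyte and interstitial macrophage (10, 0.429), lung epithelium (10, 0.0888) and sex-linked (5, 0.880) lists had no passing member over all genes, and adjusted over the list alone 2 monocyte and interstitial macrophage markers rose. The NK cell, mast cell and erythroid lists had 1 tested member each, none passing over all genes, and the B cell list had 0, so they were not tested as lists. With 1 member, adjustment over the list alone changes nothing. The mast cell gene's rise therefore rests on an unadjusted edgeR p of 0.0316 and is no list result. For the MHC class I, toll-like receptor, NRF2, cell cycle and sex-linked lists the median, the mean and the camera direction did not share a sign. With an estimated correlation in camera, 0 of the 33 lists passed and 5 had an unadjusted p under 0.05. Fry called 6 lists, 4 of them among the 7 of camera. It did not call MHC class II presentation (fry adjusted p = 0.144), phagocytic and scavenger receptors (0.0912) or stromal and endothelial markers (0.170), and it called LXR and PPAR targets (0.0193) and dendritic cell markers (0.0365). Without libraries 4 and 8, the lists of neutrophil and monocyte chemokines (camera adjusted p = 0.0327), NF-kB genes (0.0123), LXR and PPAR targets (0.0345) and T cell markers (0.0123) also passed. Without library 1, 5 or 6 the lists passing by camera with the preset correlation numbered 11, 11 and 12.

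With table position as a block, the pairing chosen after the data were seen, 9 lists passed by camera. They were the 7 that passed without it and the lists of mitochondrial transcripts and lipid synthesis. None passed with an estimated correlation. Members rose and fell in numbers of 3 and 0 for T and NK cell chemokines, 4 and 2 for neutrophil and monocyte chemokines, and 2 and 3 for alternative activation. The numbers were 6 and 2 for GTPases and 1 and 6 for the type I interferon response. They numbered 4 and 7 for AP-1 and ATF factors, 9 and 3 for NF-kB genes, and 6 and 2 for toll-like receptor sensing. There were 7 and 2 for inflammasome genes, 10 and 1 for bacterial killing and 6 and 0 for phagocytic receptors. For macrophage identity they were 6 and 4, for glycolysis 2 and 5, and for LXR and PPAR targets 1 and 4. For neutrophil markers they were 3 and 0, for stromal markers 3 and 0 and for Batf2 neighbours 4 and 3. In each of the lists given no such count here or above, at most 4 members rose and at most 1 fell.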

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

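The tests of chromosome 11 and 19 placement by random draws and around Batf2, of the pairing, of sex, and of the activation genes were chosen after the results were seen. Other splits of the 8 libraries were counted for each count given above. As many changed genes were given by 2 of the 35 splits, the real one with 123 included, so chance could not be excluded at 0.05. The other was libraries 1, 2, 5 and 6 against 3, 4, 7 and 8, which gave 3863, many times the real count. It keeps whole table positions together, with as many WT as Batf2-/- libraries on each side, and so points to a structure of the samples by table position. Of the remaining splits, libraries 1, 3, 5 and 7 against the rest gave 5 and all others gave 0. The count of splits therefore cannot part chance from this structure. The highest count of any other split in 1 direction was 2096 against 61 higher and 62 lower genes, again in 2 of 35 splits including the real one. For gene lists, 9 of 35 splits called as many as the real 7, the highest other 13. With table position as a block the real split gave 1390 changed genes and was 1 of 8 splits that part all 4 pairs, the highest other giving 0; with 8 splits a share under 0.05 could not be reached.

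Single libraries stood far from the other 3 of their group in 10 of 196 groups of 4 values tested, where chance gives about 1 in 20 groups and 9.8 were to be counted by chance. In WT, library 4 was at 2.66 CPM for Pkdcc (others 4.54 to 4.83), 264 CPM for Cxcl10 (283 to 285), 7.68 CPM for Batf3 (4.42 to 4.85) and 7.80 CPM for Ccl22 (12.5 to 12.8), and library 2 was at 19.8 CPM for Jdp2 (16.7 to 17.0). In Batf2-/-, library 5 was at 64.6 CPM for Endod1 (39.7 to 41.7) and 110 CPM for Fcgr2b (82.8 to 84.3), and library 8 was at 13.5 CPM for Saa3 (5.95 to 6.35), 46.8 CPM for S100a8 (21.1 to 25.5) and 71.0 CPM for Mcemp1 (36.0 to 37.4).

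Libraries at the same place under the 2 genotype headings deviated from their group means together, with correlations across genes of 0.60, 0.50, 0.27 and 0.76 for the pairs 1 and 5, 2 and 6, 3 and 7, and 4 and 8, and 8 of 8 libraries correlated best with their own place. Chance pairing was argued against, since 1 of 24 ways of pairing, the real one, gave so high a mean (0.532; next 0.351). Sex as the whole source was argued against, since differences between same-sex libraries still correlated at 0.395 in females and 0.673 in males. A trend with transcript length and GC content as the whole source was argued against, the lowest pair correlation being 0.279 after its removal, although the trend held 37.6% of the variance of library 4's deviations. A shared day or batch of cell preparation may lie behind the pairs, which the labels neither state nor exclude and which was not tested.

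Changed genes were crowded on chromosome 11, with 8 in a window of 100 tested genes (67025154 to 73172685), while chromosome 19 as a whole did not pass (adjusted p = 0.115). Random placement was argued against (share of 10000 draws 0.0076), but 2 of 34 other splits had 8 among as many top genes, so the crowding may be of the ordinary kind. Within 20 Mb of Batf2, leaving Batf2 out, 7 of 234 tested genes changed (2.99%) against 1.06% elsewhere. The odds ratio was 2.87 (Fisher's exact test, two-sided, p = 0.0150). Sequence of another strain kept around the targeted locus is a hypothesis for this share. Majin and Snx15 are counted among the 7 and lie close to Batf2, so a direct effect of the targeted allele on them cannot be told apart from it. The odds ratio was not computed without them, so it cannot by itself decide for sequence of another strain. The other changed genes, Prune2, Gcnt1, Mamdc2, Carnmt1 and Cep78, start between 15955773 and 23302609, and no tested gene between Majin and them changed. Besides the genes of the naming rule, 3 of the 7 were chosen after their values were seen: Mamdc2 fell from 1.93 ± 0.455 to 0.0997 ± 0.154 CPM, Carnmt1 fell 1.47-fold and Cep78 rose 1.85-fold, the calls of these last genes ending without any single library (adjusted p 0.0610 to 0.236) and that of Mamdc2 without library 1, 2, 3 or 7 (0.0590 to 0.1004). The origin of the alleles, and any such region on chromosome 11, was not tested, as reads were not used here.

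Activation genes moved in both directions. S100a8 and S100a9 together were higher by 10.0 ± 6.87 CPM (SE, without the block) and Il1b by 188 ± 27.6 CPM. As a test of more neutrophils as the source of Il1b, the comparison rests on S100a8, since S100a9 was almost uncounted. It also needs the ratio of these genes in neutrophils, which was not measured. The neutrophil marker list passed upward (camera adjusted p = 0.00684, or 0.187 with an estimated correlation), so more neutrophils were not excluded. Only 5 of its 21 members were tested, and their estimated inter-gene correlation was -0.232. S100a8 and Mcemp1 were highest in library 8, while Cxcr2 was higher in all 4 Batf2-/- libraries than in any WT library. Of the 5 changed activation effectors, 0 lay on chromosomes 11 and 19, so their own position there is not the source. Whether changed genes on those chromosomes act on effectors elsewhere was not tested. Nos2 and Il12b do lie on chromosome 11. A weaker stimulation that lowers the whole response was given a bound of -0.3 for list medians on the log2 scale. The median log2 fold changes lay above it, at -0.0862 (bootstrap SE 0.0303) for the type I interferon list and 0.0507 (0.0547) for the NF-kB list. These SEs resample list members, which are correlated (estimated inter-gene correlations 0.349 and 0.236), and do not measure the spread between libraries. The comparison therefore cannot exclude a weaker stimulation. The MHC class II list passed downward with a median of -0.19. In the type I interferon list 6 members fell and 1 rose with the block. All 123 genes, the 5 changed effectors included, were among the 1390 that passed with the block. Each table position holds 1 library of each genotype, so the block could hardly remove these calls. A deviation shared alike by both libraries of a position cancels from the difference between genotypes. The block does not test a deviation that differs between them as the source of these calls. A selective effect of genotype remains a hypothesis, with chance not excluded by the counts of splits.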

How the results depend on the processing

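No paired analysis by the labels' replicate numbers was possible because the count columns carry none. A replicate block on table position, chosen after the data were seen, gave 1390 changed genes (772 higher, 618 lower), all 123 included; that 8 of 8 libraries correlated best with their own position is a hint from the data and not the design. With it Nos2 passed (adjusted p = 9.84e-06; 9.84e-06 to 1 over its 20 alternatives, 3 of them passing), as did Tnf (0.00311; up to 1) and Il6 (0.00568; up to 1). The other alternatives added after the data were seen were sex as a covariate and leaving out libraries or chromosomes. Batf2 kept its call in all settings run. DESeq2 gave 343 changed genes (212 higher, 131 lower) and limma-voom with library quality weights 370 (227 and 143), each including all 123; the test against a 1.5-fold change gave 29 (10 and 19) and an adjusted p under 0.01 gave 47 (19 and 28), fewer by construction. Without libraries 4 and 8 there were 206 changed genes (133 higher), 114 of them shared, and 12 lists passed; without chromosomes 11 and 19 there were 40 higher genes, fewer genes being tested. Leaving out each library gave 43 to 142 changed genes, 17 to 83 higher and 26 to 59 lower, and 7 to 12 lists against 7. For lists, 2 passed at 0.01 and 0 with an estimated correlation in camera, where 5 had an unadjusted p under 0.05 and fry called 6. The cause was not tested for DESeq2, quality weights, libraries 4 and 8 or single libraries. Other normalizations, filters, limma-voom and sex gave counts within 1.5 times the main ones, and no scaling moved the median log2 fold change by more than 0.0109.

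Of 50 named genes other than Batf2 that passed, 12 of them outside the rule and chosen because they passed, 16 kept the call in all alternatives run, 34 lost it in the test against 1.5-fold and 4 without libraries 4 and 8. Of 42 that did not pass, Zbtb46 not counted, 30 passed with the block on table position, none against its direction. Dok7, Col5a3, Slpi, Creb1, Fcgr2b and Snx15, and outside the rule Carnmt1, Cep78 and Ptger2, also lost the call under another scaling or filter. No named gene's call reversed; 22 values of genes that did not pass changed sign. In counts simulated without a shared deviation of pairs, the unblocked test recovered 84% of 2-fold and 2% of 1.5-fold changes. With a shared deviation of SD 0.25 (log2), and with each gene's dispersion divided by 4, it recovered 78% and 6%. The block then recovered 100% and 90%, with 5.56% of calls false. Because the dispersions were lowered as well, these shares do not give the power of the block in the real data.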

Other observations

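The genes given here lie outside the rule for named genes and were chosen after their values were seen, with no list or enrichment test behind them. Ptges, which makes prostaglandin E2, rose 2.35-fold from 78.4 ± 4.70 to 184 ± 40.8 CPM (SD, n = 4; edgeR adjusted p = 0.00625), and Ptger2, a receptor for it, fell 1.86-fold (adjusted p = 0.0475). Entpd1, the CD39 ectonucleotidase on chromosome 19, fell 1.88-fold from 253 ± 35.8 to 135 ± 18.99 CPM (adjusted p = 0.0207), and Adora2b, an adenosine receptor on chromosome 11, fell 3.66-fold from 1.35 ± 0.0762 to 0.366 ± 0.0961 CPM (adjusted p = 0.00485). Of these, Ptges and Adora2b kept the call without any single library, Entpd1 lost it without library 1, 2, 3, 6 or 7 (0.0543 to 0.0901) and Ptger2 without any library (0.0517 to 0.187).

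Il7r, like the other genes here chosen after its values were seen, rose 2.10-fold from 58.2 ± 10.3 to 122 ± 21.4 CPM (edgeR adjusted p = 0.0151; SD, n = 4) and Il18rap rose 1.89-fold (adjusted p = 0.00870). Procr, the protein C receptor, fell 1.89-fold from 632 ± 104 to 334 ± 53.8 CPM (adjusted p = 0.0316), while F3, tissue factor, rose 1.98-fold at a low level, from 1.79 ± 0.370 to 3.54 ± 0.437 CPM (adjusted p = 0.0360). Without library 3 all 4 lost the call, with Il18rap at 0.0713. Il7r lost it without library 2, 3 or 7 (0.0658 to 0.0816), Procr without library 1, 3, 4, 5, 6 or 7 (0.0740 to 0.177) and F3 without library 1, 2, 3, 5, 6 or 7 (0.0816 to 0.133). Acap1, on chromosome 11, rose from 0.695 ± 0.180 to 4.92 ± 0.840 CPM (adjusted p = 3.94e-04).

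S100a9, chosen after its values were seen, had 2 counts over all 8 libraries, at most 1 in a library, while its partner gene S100a8 had 6882.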
